A study of Homo sapiens with 65 samples.

How the data were processed

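Total RNA of differentiating cells of the H9 reporter line and of its derivative without the RUNX1 DNA-binding domain was sequenced from TruSeq libraries. The mesoderm protocol gave unsorted cells of day 0, 2 and 4 and cells of day 7 and 12 sorted on SOX17, CD34 and CD43, and the endoderm protocol gave unsorted WT cells of day 0, 2, 4 and 7. The 65 libraries formed 19 groups by protocol, day, genotype and gate, taken from the sample titles. The titles of the KO samples of day 2 and day 4 say KO while the genotype field does not, and these groups follow the titles. The single KO SOX17-negative CD43-negative library of day 12 entered no test.

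The deposited count table holds raw fragment counts per gene, and the authors also gave log2 RPKM values, computed as log2 of TMM-scaled RPKM plus 1. The labels name cutadapt 1.18, featureCounts and R 3.2.2 and the genome build GRCh38, without roles. The aligner, the annotation release and the gene lengths behind the RPKM are not given in the sources used here. Zeros coincide between both tables, and the log2 RPKM values follow the counts with 1 factor per gene and 1 per library. Of 58302 gene identifiers, 58039 were named from GENCODE 29 and 263 have no symbol there. Libraries held between 10366048 and 19081031 counts. Reads of genes with near-identical sequence, such as HBA1 and HBA2 or HSPA1A and HSPA1B, cannot be assigned to 1 of them with certainty. Within groups no pair of libraries held the same counts, as these 85 pairs had a chi-square per gene between 4.47 and 88.23 over genes with a mean count of at least 20.

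Differential expression was tested with edgeR 4.0.16 in R 4.3.3, by quasi-likelihood F tests on the counts with TMM factors, a design of 1 mean per group and contrasts between groups. Genes passed filterByExpr by group with a minimum count of 10 and a minimum total of 15. The 6 fits were the 24 unsorted mesoderm libraries (21612 genes), the 12 endoderm libraries (21542 genes), the 21 WT libraries of day 0, 2 and 4 of both protocols (22664 genes), the 28 sorted libraries in groups with replicates (22978 genes), and the separate pairs of day 7 against day 4 (8 libraries, 20028 genes) and of endoderm against endothelium of day 7 (7 libraries, 21165 genes). The common biological coefficient of variation was 0.227, 0.138, 0.192, 0.172, 0.193 and 0.136 in this order. Differences of differences compared the protocols by their change from day 0, the KO effect between day 7 and day 12, and the SOX17 difference between genotypes. A gene is called changed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of the fit. The standard error is the absolute log2 fold change divided by the square root of F. Fold changes are given only for genes with more than 3 counts in each compared group. With 0 counts in a group a lower bound against 3 counts over the group is given, and with 1 to 3 counts the ratio with its 95 % counting interval, which covers counting error alone.

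A total of 25 gene lists with 290 entries were fixed before the data were examined, as were the comparisons, the tests and the alternatives, except where a choice is said to have been made after seeing the data. Lists were tested with camera of limma 3.58.1 with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. Some genes stand in more than 1 list, such as SOX17 and CXCR4 in those of arteries and of definitive endoderm. The genes named are members of these lists and, outside them, up to 6 highest and 6 lowest genes per comparison that passed, had a mean log2 CPM of at least 3 in the higher group and did not overlap between the compared libraries. Examples from a list were to be its members of largest change past the threshold. After the alternatives had been run, several genes whose calls ended under one of them, such as UNC5B, NFE2 and PRTN3, were replaced or left out, and a member that moved against the rest of its list was in places named as well. RUNX1, SOX17, CD34 and SPN were named in any case. Between sorted fractions they check the gates and are not findings.

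On simulated unchanged and changed groups built from these counts, changes of 1.5-fold were recovered for 1.5 to 34.3 % of the changed genes, changes of 2-fold for 29.9 to 79.1 % and changes of 4-fold for 68.2 to 92.4 %, with 2 to 14 false calls per comparison. The alternatives were median-of-ratios size factors in edgeR, no filter on low counts, DESeq2 1.42.0, limma-trend on the deposited log2 RPKM of the authors, the compared groups alone, the replicate number as a block, runs of consecutive library numbers as a block in the sorted libraries, and each library left out in turn. Replicate numbers were taken to pair the libraries where the deviations from the group means of every pair correlated by at least 0.1 across genes, which held for KO against WT at day 0, at day 2 and in SOX17-positive cells, for WT SOX17-positive cells over time, for endoderm of day 4 against day 2 and for endoderm against endothelium of day 7. By the same measure library runs, but not replicate numbers, paired KO against WT in SOX17-negative cells of day 7 (3 pairs, 0.15 to 0.29) and SOX17 in KO at day 7 (3 pairs, 0.22 to 0.51), where KO SOX17-negative number 3 goes with number 4 of the other groups. The overlap of a pair of comparisons that share WT libraries was computed again with these libraries divided between them. Other splits of the libraries were counted for comparisons of groups of at least 3, all of them, or 50 drawn at random for differences of differences.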

Results

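The H9 reporter line (SOX17-mCherry, RUNX1C-GFP) and its derivative without the DNA-binding domain of RUNX1, called WT and KO here, were profiled along a protocol towards haematopoietic mesoderm, and WT also along an endoderm protocol. The 65 libraries formed 19 groups, of which 18 had replicates. Gene changes are given as log2 fold change ± standard error, and levels as mean CPM, the counts scaled to library size, ± SD between libraries. Of the 621 tests of gene lists, 196 passed with a preset correlation between genes, and 84 of these passed with an estimated correlation. Not every list that passed is named, and each list named is given with both adjusted p-values. Whether the replicates were separate cultures is not given in the sources used here, so the p-values measure the spread between libraries. The exact binomial test of HSD17B7P2 is the exception and covers counting error alone.

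From day 0 to day 2 of the mesoderm protocol (4 WT libraries at each day), pluripotency transcripts fell while those of the primitive streak and of lateral mesoderm rose. SOX2, a core pluripotency factor, changed by -10.07 ± 0.47, PRDM14 by -5.67 ± 0.33 and NANOG by -5.61 ± 0.38. In the pluripotency list 10 of 14 tested members fell (10 adjusted over the list alone), with adjusted p = 2.35e-15, and adjusted p = 0.000455 with an estimated correlation. TBXT, the T-box factor of the streak, was 8790-fold (95 % counting interval 2430 to 72500) higher at day 2. EVX1 was at least 6620-fold higher and SP5, a Wnt target, at least 2100-fold higher, both without a count at day 0. MESP1, a factor of nascent mesoderm, rose by 10.02 ± 0.41. In the primitive streak list 12 of 14 tested members rose (12 adjusted over the list alone), with adjusted p = 4.45e-30, and adjusted p = 1.9e-07 with an estimated correlation. In the lateral mesoderm list 13 of 14 tested members rose (13 adjusted over the list alone), with adjusted p = 4.85e-23, and adjusted p = 7.13e-07 with an estimated correlation. HAND1, a factor of lateral and extraembryonic mesoderm, was 18600-fold (95 % counting interval 5150 to 154000) higher at day 2. APLNR, the apelin receptor, and MSX1 rose by 12.78 ± 0.49 and 9.71 ± 0.43.

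Targets of BMP and Wnt signalling rose over the same 2 days. In the BMP target list 7 of 7 tested members rose (7 adjusted over the list alone), with adjusted p = 4.31e-18, and adjusted p = 0.000198 with an estimated correlation. MSX2 rose by 8.67 ± 0.33, ID2 by 5.59 ± 0.25 and SMAD6 by 5.13 ± 0.26. In the Wnt target list 7 of 8 tested members rose (7 adjusted over the list alone), with adjusted p = 1.93e-11, and adjusted p = 0.00139 with an estimated correlation. DKK1, a secreted Wnt inhibitor, rose by 10.00 ± 0.82 and LEF1 by 8.01 ± 0.48. Among the HOXA and CDX genes 12 of 14 tested members rose (12 adjusted over the list alone), with adjusted p = 4.35e-09, and adjusted p = 0.0881 with an estimated correlation. GATA6, which mesoderm and endoderm share, rose by 11.10 ± 0.46. SOX17 was 1300-fold (95 % counting interval 233 to 51200) higher at day 2, at 22.82 ± 10.41 CPM. LEFTY2, a Nodal inhibitor, fell by 7.16 on the log2 scale. In all 9739 of 21612 tested genes changed, 4799 upwards and 4940 downwards. Library number 1 of day 0 stood apart in both genotypes, with EGR1, an immediate early gene, at 107 CPM in WT and 108 CPM in KO against 3.74 to 24.5 CPM in the other d0 libraries. The share of counts from mitochondrial genes was 3.44 ± 0.56 % at day 0 and 5.26 ± 0.35 % at day 2.

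Between day 2 and day 4 the streak genes fell and endothelial and mesenchymal transcripts rose (4 WT libraries at each day). In the primitive streak list 14 of 14 tested members fell (14 adjusted over the list alone), with adjusted p = 1.16e-24, and adjusted p = 2.52e-07 with an estimated correlation. EOMES, a T-box factor, changed by -10.75 ± 0.94, MESP1 by -9.06 ± 0.37 and MIXL1 by -8.83 ± 0.43. In the pan-endothelial list 16 of 17 tested members rose (16 adjusted over the list alone), with adjusted p = 8.18e-12, and adjusted p = 0.114 with an estimated correlation. CDH5, the endothelial cadherin, rose by 10.12 ± 0.93, PECAM1 by 8.38 ± 0.81 and ESAM by 7.14 ± 0.96. In the list of mesenchyme and smooth muscle 10 of 12 tested members rose and 2 fell (10 rose and 2 fell adjusted over the list alone), with adjusted p = 0.000516, and adjusted p = 0.221 with an estimated correlation. COL3A1, a fibrillar collagen, rose by 8.39 ± 1.03 and LUM by 6.85 ± 0.88.

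TAL1, a transcription factor of haemangioblasts, rose by 7.61 ± 0.50 from day 2 to day 4, CD34 by 8.03 ± 0.82 and RUNX1 by 1.96 ± 0.69. RUNX1 no longer passed without WT number 1 of day 4 or of day 2, with adjusted p = 0.0688 and 0.0503. Among Nodal targets 1 of 6 tested members rose and 5 fell (1 rose and 5 fell adjusted over the list alone), with adjusted p = 2.1e-05, and adjusted p = 0.00365 with an estimated correlation. CER1 changed by -10.71 ± 0.77 and NODAL itself by -8.25 ± 0.44. In the pluripotency list 12 of 14 tested members fell (12 adjusted over the list alone), with adjusted p = 2.45e-09, and adjusted p = 0.00763 with an estimated correlation, and POU5F1 changed by -5.84 ± 0.35. The comparison held 11112 changed genes, 5608 higher and 5504 lower at day 4. COL3A1 was 187 CPM in WT number 3 of day 4, while the highest of the group held 4109 CPM. Without WT number 3 and KO number 4 of day 4, a choice made after seeing the data, 11617 genes changed. The mitochondrial share was 3.45 ± 0.28 % at day 4, against 5.26 ± 0.35 % at day 2.

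The KO and WT lines were compared on each of these days with 4 libraries a side. RUNX1 was 0.94 ± 0.615 CPM in KO and 2.77 ± 3.28 CPM in WT at day 0, where WT number 1 held 7.67 CPM and the other 3 WT libraries 1.14 CPM on average. The levels were 10.2 ± 9.01 and 10.7 ± 1.95 CPM at day 2, and 30.9 ± 26.1 and 41.6 ± 18.4 CPM at day 4. CDH5 was 99.5 ± 92.1 CPM in KO and 103 ± 37.1 CPM in WT at day 4, and COL3A1 2058 ± 1915 and 2454 ± 1666 CPM. With edgeR, 0 genes passed at day 0, 0 at day 2 and 0 at day 4. An unadjusted p under 0.05 was found for 146, 973 and 987 of 21612 genes. On each day these are fewer than the share of 0.05 that chance alone would give. No list passed on any of the 3 days. DESeq2 called 0 genes at day 0, 15 at day 2 and 2 at day 4, and limma-trend 0, 0 and 1. With the spread taken from the 8 compared libraries alone, 143 genes passed at day 2 and 0 at day 0 and at day 4. With replicate number as a block, 0 genes passed on each of the 3 days. At day 4, 3 genes passed without KO number 1, 2 without KO number 3 and 1 without WT number 2. In simulated data, the same design recovered 83.3 % of the genes changed by 4-fold at day 0, 80.3 % at day 2 and 83.3 % at day 4. Of those changed by 2-fold it recovered 46.3, 37.3 and 52.2 %, and of those changed by 1.5-fold 22.4, 20.9 and 20.9 %, so effects of KO, smaller ones above all, can have been missed. The simulated libraries varied independently, without the pairing seen in the real ones at day 0 and day 2, so the real recovery can differ. HSD17B7P2, with few counts and named after its values were seen, was not called. It lay lower in every KO library than in every WT library on each day. The mitochondrial share at day 4 was 4.42 ± 0.79 % in KO and 3.45 ± 0.28 % in WT. The titles of the KO samples of day 2 and day 4 say KO while their genotype field does not name the deletion, and the groups follow the titles.

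Sorted SOX17-positive endothelium of day 7 was compared with unsorted cells of day 4 (4 WT libraries each). EMCN, a sialomucin of endothelium, was higher by 10.48 ± 0.33, VWF by 6.84 ± 0.38 and CLDN5, of tight junctions, by 6.83 ± 0.45. In the pan-endothelial list 17 of 18 tested members rose (17 adjusted over the list alone), with adjusted p = 6.9e-20, and adjusted p = 0.109 with an estimated correlation. In the arterial list 11 of 14 tested members rose (11 rose and 1 fell adjusted over the list alone), with adjusted p = 2.71e-08, and adjusted p = 0.136 with an estimated correlation, led by DLL4, a Notch ligand, at 7.49 ± 0.47. Lateral mesoderm genes were mostly lower at day 7, where 2 of 14 tested members rose and 11 fell (2 rose and 11 fell adjusted over the list alone), with adjusted p = 3.3e-08, and adjusted p = 0.021 with an estimated correlation. GATA4 changed by -6.21 ± 0.37 and MSX2 by -5.56 ± 0.18. In the Wnt target list 7 of 8 tested members fell (7 adjusted over the list alone), with adjusted p = 1.15e-06, and adjusted p = 0.021 with an estimated correlation, including NOTUM at -6.70 ± 0.71. Among cell cycle genes 12 of 12 tested members fell (12 adjusted over the list alone), with adjusted p = 8.38e-09, and adjusted p = 0.126 with an estimated correlation, including CCNB1 at -2.28 ± 0.13. RUNX1 rose by 1.35 ± 0.28. A total of 12586 genes differed, with 6358 higher at day 7. The mitochondrial share was 5.67 ± 0.46 % at day 7 and 3.45 ± 0.28 % at day 4. Day, sorting and library-number series coincide in this comparison.

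**Figure D1:**
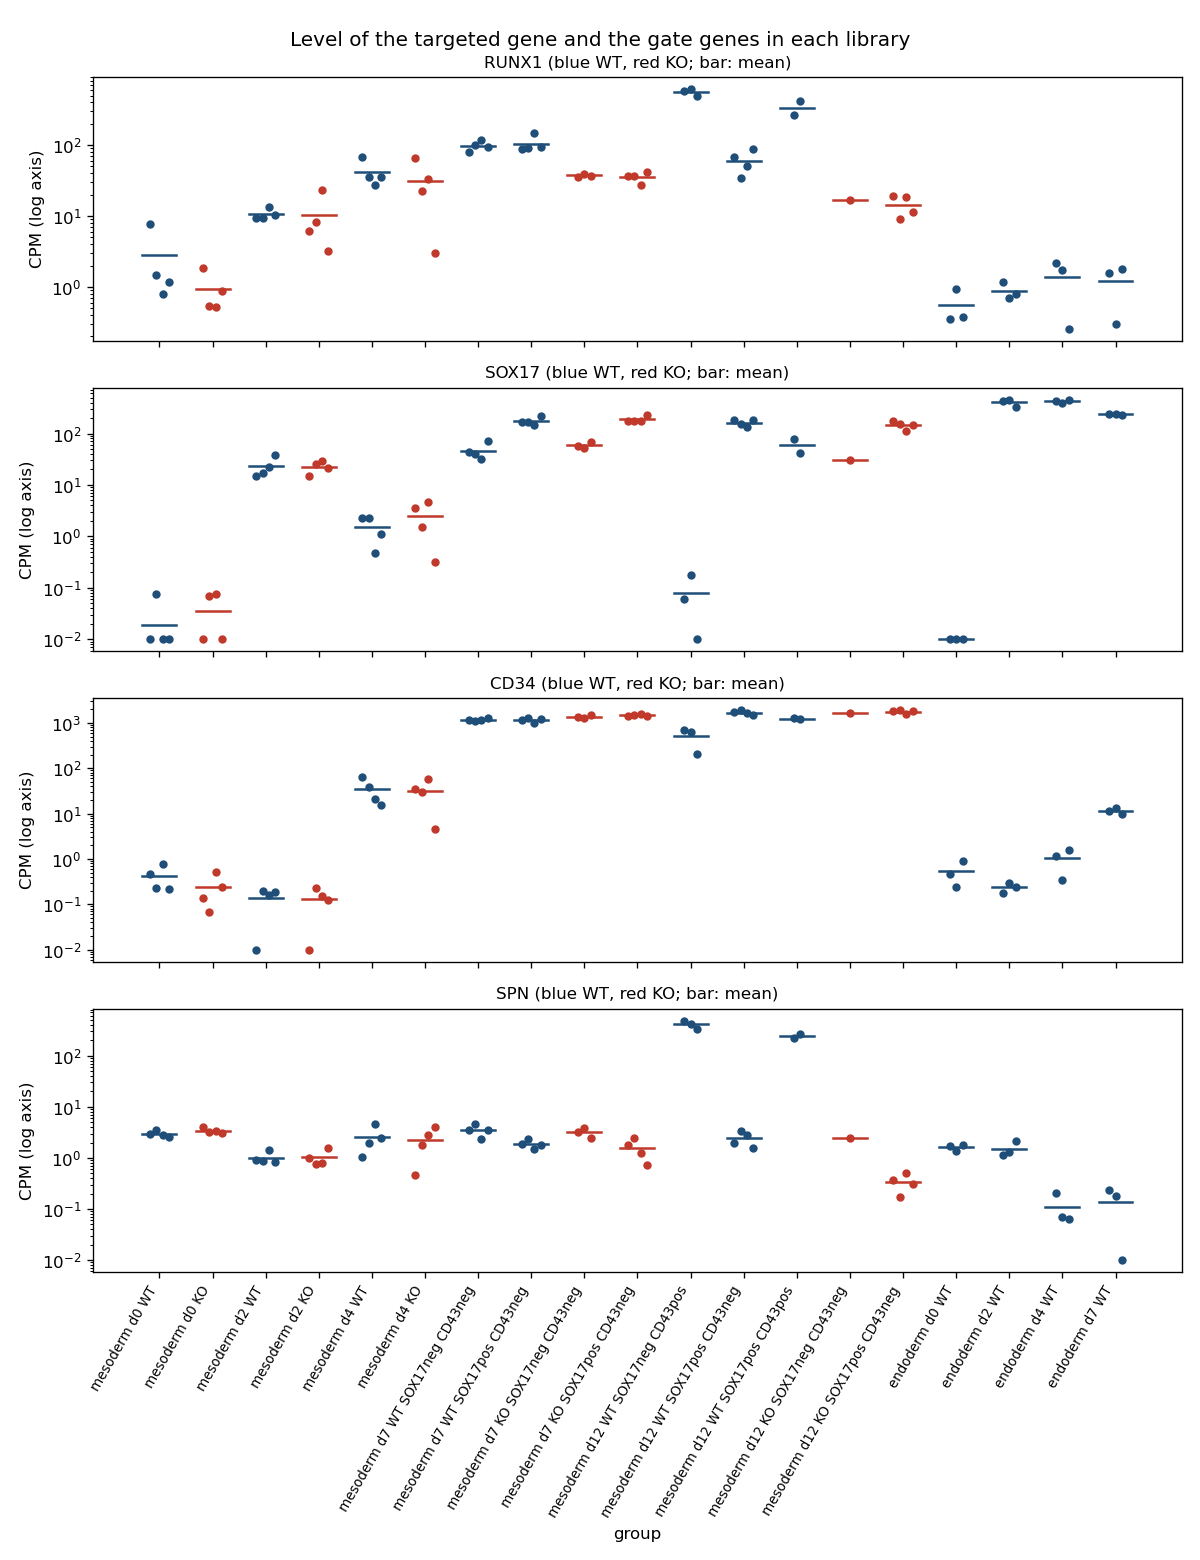
Level in CPM (log axis, values under 0.01 drawn at 0.01) of RUNX1, SOX17, CD34 and SPN in each library (points) by group, with the mean of the group (bar). RUNX1 was lower in every KO SOX17-positive library than in every WT one at day 7 and at day 12.

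At day 7, CD34-positive CD43-negative WT cells were split by SOX17 (4 libraries a side). Arterial genes were higher in the SOX17-positive fraction, where 8 of 15 tested members rose (12 adjusted over the list alone), with adjusted p = 1.91e-21, and adjusted p = 0.0113 with an estimated correlation. SOX17, the gate, is a member of this list, and without it 7 of 14 tested members rose (11 adjusted over the list alone), with adjusted p = 2.78e-16, and adjusted p = 0.0139 with an estimated correlation. CXCR4, a chemokine receptor, was higher by 2.95 ± 0.55 and NOTCH4 by 1.40 ± 0.20. SOX17 itself differed by 1.92 ± 0.21. Among Notch targets 2 of 7 tested members rose (5 adjusted over the list alone), with adjusted p = 2.54e-06, and adjusted p = 0.0588 with an estimated correlation, and NRARP was higher by 1.40 ± 0.30. Outside the lists PRND differed by 5.48 ± 0.33 and CARTPT by 4.89 ± 0.61. Haematopoietic transcription factors were lower in the SOX17-positive fraction, where 4 of 16 tested members fell (9 adjusted over the list alone), with adjusted p = 2.32e-11, and adjusted p = 0.0113 with an estimated correlation. KLF1, an erythroid factor, differed by -3.46 ± 0.73 and CBFA2T3 by -1.92 ± 0.28. KLF1 no longer passed without SOX17-positive number 1 or 4 or SOX17-negative number 4, with adjusted p = 0.0605, 0.0678 and 0.0755, nor NRARP without SOX17-positive number 4, with adjusted p = 0.0869. In the lateral mesoderm list 3 of 14 tested members fell (7 adjusted over the list alone), with adjusted p = 1.27e-07, and adjusted p = 0.0113 with an estimated correlation. Transcripts of mesenchyme, another cell type that the gate could hold, were lower too, as 3 of 12 tested members fell (7 adjusted over the list alone), with adjusted p = 3.7e-09, and adjusted p = 0.0509 with an estimated correlation. LUM differed by -2.35 ± 0.45. SOX17-negative number 4 stood apart from its group, with a chi-square per gene between 65.99 and 88.23 against the other 3 libraries, which had 5.82 to 24.16 among themselves. Without it, a choice made after seeing the data for the lists, 3 of 15 arterial genes and 1 of 7 Notch targets rose, while 2 of 16 haematopoietic transcription factors, 1 of 14 lateral mesoderm genes and 2 of 12 genes of mesenchyme and smooth muscle fell. Each of these lists still passed with the preset correlation. With an estimated correlation they had adjusted p = 0.00984, 0.0361, 0.00645, 0.0119 and 0.0542 in this order. RUNX1 was 104 ± 28.9 CPM in the SOX17-positive and 97.6 ± 14.7 CPM in the SOX17-negative fraction.

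In WT 367 genes differed between the SOX17 fractions, 213 of them higher with SOX17. Other settings gave 208 to 651 genes. The count was 166 without SOX17-positive number 4, 219 without SOX17-positive number 1 and 235 without SOX17-negative number 4. In KO (4 SOX17-positive and 3 SOX17-negative libraries) 154 genes differed, 80 higher with SOX17. PRND differed by 3.33 ± 0.28, CARTPT by 3.30 ± 0.59 and NOTCH4 by 1.495 ± 0.215. In the arterial list 2 of 15 tested members rose (10 adjusted over the list alone), with adjusted p = 5.91e-17, and adjusted p = 0.0168 with an estimated correlation, and without SOX17 1 of 14 rose (9 adjusted over the list alone), with adjusted p = 9.23e-13, and adjusted p = 0.0321 with an estimated correlation. In the list of mesenchyme and smooth muscle 1 of 12 tested members fell (7 adjusted over the list alone), with adjusted p = 6.63e-10, and adjusted p = 0.0332 with an estimated correlation. In the lateral mesoderm list 2 of 14 tested members fell (6 adjusted over the list alone), with adjusted p = 7e-08, and adjusted p = 0.0168 with an estimated correlation. Among haematopoietic transcription factors 1 of 16 tested members fell (2 adjusted over the list alone), with adjusted p = 3.79e-06, and adjusted p = 0.0544 with an estimated correlation. Library runs, taken from consecutive library numbers, paired the libraries in KO, and with runs as a block 376 genes passed. With that block lateral mesoderm and mesenchyme no longer passed with an estimated correlation, with adjusted p = 0.0525 and 0.104. Other settings gave 159 to 612 genes in KO. The KO count was 46 without SOX17-negative number 2, 74 without number 3 and 89 without number 1. Without SOX17-positive number 3, 1 or 4 it was 61, 89 and 94. The test of whether the SOX17 difference depended on genotype passed 0 genes with edgeR, 240 with an unadjusted p under 0.05, 0 with DESeq2 and 0 with limma-trend, and no list passed. The 240 are fewer than a share of 0.05 of the 22978 tested genes. With replicate number as a block, arterial genes passed with adjusted p = 0.00454, and adjusted p = 0.775 with an estimated correlation, and Notch targets with adjusted p = 0.004, and adjusted p = 0.275 with an estimated correlation, both towards a smaller SOX17 difference in KO. Without SOX17 the arterial list had adjusted p = 0.0165 with that block, and adjusted p = 0.775 with an estimated correlation.

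RUNX1 was lower in KO than in WT SOX17-positive cells of day 7, at 35.3 ± 5.85 against 104 ± 28.9 CPM (4 libraries each), a change of -1.54 ± 0.24 with adjusted p = 0.00514. Deletion of the DNA-binding domain need not lower a count over the whole gene. GFI1, a repressor of endothelial genes downstream of RUNX1, was lower by -3.94 ± 0.75, at 0.151 ± 0.049 against 2.42 ± 2.21 CPM. VANGL2, of planar cell polarity, and IL17RD, an antagonist of FGF signalling, were higher in KO by 1.43 ± 0.17 and 1.12 ± 0.22. Among haematopoietic transcription factors 2 of 16 tested members fell (4 adjusted over the list alone), with adjusted p = 4.79e-06, and adjusted p = 0.121 with an estimated correlation. RUNX1, the edited gene, is among the 2. RUNX1 no longer passed without WT number 3 (adjusted p = 0.0561) or KO number 3 (adjusted p = 0.0677). GFI1 did not pass without WT number 2 or 3 or any 1 KO library (adjusted p = 0.0659 to 0.319), with the compared groups alone (adjusted p = 0.144) or with limma-trend (adjusted p = 1). IL17RD did not pass without any 1 of the 8 libraries (adjusted p = 0.0867 to 0.253). In the RUNX family list 1 of 4 tested members fell (1 adjusted over the list alone), with adjusted p = 0.0154, and adjusted p = 0.121 with an estimated correlation. The member that fell is RUNX1, the gene edited in KO, and no list was tested without it. That list had a median log2 fold change of 0.02 and a mean of -0.25, and its test gave a lower level. It therefore shows nothing beyond RUNX1 itself. MYB was 29.96 ± 7.78 CPM in KO and 48.2 ± 6.97 CPM in WT. Among cell cycle genes 0 of 12 tested members passed (0 adjusted over the list alone), with adjusted p = 4.79e-06, and adjusted p = 0.706 with an estimated correlation towards lower levels. In the pan-endothelial list 0 of 18 tested members passed (0 adjusted over the list alone), with adjusted p = 0.00585, and adjusted p = 0.954 with an estimated correlation, towards higher levels in KO.

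In these SOX17-positive cells of day 7, 13 genes differed, 2 higher and 11 lower in KO. The deviations of the libraries paired by replicate number, and with that number as a block 18 genes passed. DESeq2 called 30 genes. The count was 2 without WT number 3, 2 without KO number 3 and 3 without KO number 1. It was 5 without WT number 2, KO number 2 or KO number 4, and 7 without WT number 4. In SOX17-negative cells (4 WT and 3 KO libraries) 2 genes differed, VANGL2 by 1.04 ± 0.17 and the pseudogene HSD17B7P2, at 0.0401 ± 0.0351 CPM in KO and 2.65 ± 0.395 CPM in WT, a gene named after its values were seen. RUNX1 was 37.3 ± 2.14 CPM in KO and 97.6 ± 14.7 CPM in WT, with adjusted p = 0.0617. RUNX1 passed there without a filter on low counts (adjusted p = 1.92e-05), with DESeq2 (adjusted p = 0.00045), with limma-trend (adjusted p = 0.0447) and with the compared groups alone (adjusted p = 0.03). Among haematopoietic transcription factors 0 of 16 tested members passed (7 fell adjusted over the list alone), with adjusted p = 1.52e-11, and adjusted p = 0.0174 with an estimated correlation, towards lower levels in KO. RUNX1, the edited gene, is a member of that list, which was not tested without RUNX1. WT number 4, the library that stood apart, is in this comparison, and without it that list had adjusted p = 4.06e-08, and adjusted p = 0.0155 with an estimated correlation. Library runs paired these libraries, and with runs as a block 7 genes passed, and that list had adjusted p = 1.62e-07, and adjusted p = 0.113 with an estimated correlation. In the arterial list 0 of 15 tested members passed (0 adjusted over the list alone), with adjusted p = 0.0113, and adjusted p = 0.6 with an estimated correlation, towards higher levels in KO, and with runs as a block it had adjusted p = 0.0781, and adjusted p = 0.855 with an estimated correlation. The block of replicate numbers gave 7 genes, DESeq2 13 and limma-trend 8. Without KO number 1, KO number 2, WT number 3 or WT number 4, 1 gene passed, and VANGL2 had adjusted p = 0.114 to 0.447.

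SOX17-positive CD43-negative cells changed between day 7 and day 12 (4 libraries a side). In WT, LYVE1, a hyaluronan receptor of venous and lymphatic endothelium, rose by 5.50 ± 0.67 and STAB2, a scavenger receptor, by 3.00 ± 0.70. In the venous and lymphatic list 6 of 8 tested members rose (6 adjusted over the list alone), with adjusted p = 2.22e-05, and adjusted p = 0.158 with an estimated correlation. Among the HOXA and CDX genes 7 of 13 tested members fell (10 adjusted over the list alone), with adjusted p = 6.12e-07, and adjusted p = 0.057 with an estimated correlation, and HOXA6 changed by -1.41 ± 0.25. In the list of immediate early and heat shock genes 7 of 10 tested members rose (8 adjusted over the list alone), with adjusted p = 7.69e-05, and adjusted p = 0.158 with an estimated correlation. FOSB rose by 3.12 ± 0.85 and DUSP1 by 2.83 ± 0.44. In the interferon response list 5 of 8 tested members rose (5 adjusted over the list alone), with adjusted p = 0.002, and adjusted p = 0.17 with an estimated correlation, led by IFI44L at 5.14 ± 0.71. In the cell cycle list 7 of 12 tested members fell (11 adjusted over the list alone), with adjusted p = 0.00011, and adjusted p = 0.399 with an estimated correlation, including PLK1 at -1.08 ± 0.26. LHX6 rose by 8.16 ± 0.67 and KLF4 by 5.44 ± 0.69, while GAD1 changed by -5.48 ± 0.44. MYB changed by -1.20 ± 0.21. RUNX1 was 60.2 ± 22.6 CPM at day 12 and 104 ± 28.9 CPM at day 7. In all 4090 genes changed, 1970 upwards. The libraries paired by replicate number, and the block gave 4713 genes. With the block the HOXA and CDX genes and the immediate early and heat shock genes passed with an estimated correlation as well, each at adjusted p = 0.038. The mitochondrial share was 4.57 ± 0.46 % at day 12 and 5.67 ± 0.46 % at day 7.

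In KO 3052 genes changed between day 7 and day 12, 1378 upwards, and the mitochondrial share was 5.43 ± 0.42 % and 4.51 ± 0.45 %. LYVE1 rose by 4.47 ± 0.65, STAB2 by 3.60 ± 0.72 and LHX6 by 7.43 ± 0.64. In the venous and lymphatic list 5 of 8 tested members rose (6 adjusted over the list alone), with adjusted p = 5.12e-06, and adjusted p = 0.0998 with an estimated correlation. Among the HOXA and CDX genes 8 of 13 tested members fell (9 adjusted over the list alone), with adjusted p = 1.16e-08, and adjusted p = 0.0418 with an estimated correlation. MYB, a transcription factor of blood progenitors, changed by -3.48 ± 0.25, SPI1, a myeloid factor, by -2.24 ± 0.53 and RUNX1 by -1.29 ± 0.25. Among haematopoietic transcription factors 2 of 16 tested members rose and 5 fell (2 rose and 6 fell adjusted over the list alone), with adjusted p = 0.00341, and adjusted p = 0.207 with an estimated correlation. In the leukocyte list 3 of 12 tested members fell (3 adjusted over the list alone), with adjusted p = 0.000688, and adjusted p = 0.185 with an estimated correlation, led by SPN at -2.14 ± 0.40. Limma-trend did not call SPI1 or SPN, with adjusted p = 0.107 and 0.187. The knockout effect differed between the days for 1 gene with edgeR, MYB, by -2.28 ± 0.32 with adjusted p = 0.00256. MYB was 29.96 ± 7.78 in KO and 48.2 ± 6.97 CPM in WT at day 7, and 2.72 ± 0.542 and 20.9 ± 6.29 CPM at day 12. For this difference 561 genes had an unadjusted p under 0.05, DESeq2 called 8 genes and limma-trend 0. A share of 0.05 of the 22978 tested genes would be more than the 561. The block gave 6 genes, and leaving out WT number 1 of day 12 or KO number 4 of day 7 gave 6 and 3. As groups, the haematopoietic transcription factors (adjusted p = 1.81e-10, and adjusted p = 0.0225 with an estimated correlation) and the leukocyte genes (adjusted p = 1.81e-10, and adjusted p = 0.0225 with an estimated correlation) were lowered further in KO at day 12 than at day 7. Of them 1 of 16 tested members fell (2 adjusted over the list alone) and 0 of 12 tested members passed (3 fell adjusted over the list alone). Arterial genes (adjusted p = 0.000143, and adjusted p = 0.297 with an estimated correlation) and pan-endothelial genes (adjusted p = 0.0125, and adjusted p = 0.469 with an estimated correlation) were also shifted towards lower levels in KO at day 12 relative to day 7. So were myeloid and mast cell genes (adjusted p = 1.64e-07, and adjusted p = 0.0402 with an estimated correlation). Cell cycle genes shifted towards higher levels (adjusted p = 1.22e-14, and adjusted p = 0.0508 with an estimated correlation).

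At day 12, KO SOX17-positive CD43-negative cells held less RNA of blood regulators than WT cells (4 libraries each). RUNX1 was 14.5 ± 5.03 against 60.2 ± 22.6 CPM, a change of -2.05 ± 0.25 with adjusted p = 6.27e-05, and every KO library was below every WT library. MYB changed by -2.94 ± 0.25, GFI1 by -4.43 ± 0.65 and SPI1 by -3.51 ± 0.46. Among haematopoietic transcription factors 5 of 16 tested members fell (7 adjusted over the list alone), with adjusted p = 2.99e-39, and adjusted p = 9.37e-06 with an estimated correlation. RUNX1, the gene edited in KO, is among the 5, and this list was not tested without it. Leukocyte genes were lower as well, as 5 of 12 tested members fell (8 adjusted over the list alone), with adjusted p = 2.03e-35, and adjusted p = 2.13e-05 with an estimated correlation. SPN, which encodes CD43, changed by -2.77 ± 0.37, at 0.341 ± 0.141 against 2.42 ± 0.845 CPM, inside a gate set to exclude CD43. PTPRC, the leukocyte antigen CD45, was 0.0153 ± 0.0307 CPM in KO and 0.842 ± 0.789 CPM in WT. In the list of myeloid and mast cell genes 2 of 16 tested members fell (5 adjusted over the list alone), with adjusted p = 7.45e-15, and adjusted p = 0.00121 with an estimated correlation. CSF1R, a receptor of macrophages, changed by -3.53 ± 0.48 and LYZ, lysozyme, by -2.99 ± 0.51. MPO, a granule enzyme, was 0.332 ± 0.111 CPM in KO and 0.734 ± 0.471 CPM in WT. In the interferon response list 1 of 8 tested members fell (3 adjusted over the list alone), with adjusted p = 2.58e-07, and adjusted p = 0.0113 with an estimated correlation. That member, IFI44L, changed by -2.67 ± 0.58, but did not pass with replicate number as a block (adjusted p = 0.0711) or without WT number 2 or 3 or any 1 KO library (adjusted p = 0.0615 to 0.914).

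Among arterial genes at day 12 1 of 15 tested members fell (1 adjusted over the list alone), with adjusted p = 0.000626, and adjusted p = 0.358 with an estimated correlation. That member, BMX, a kinase of arterial endothelium, changed by -4.04 ± 0.55. CDH5 was 1964 ± 316 CPM in KO and 2073 ± 174 CPM in WT, and SOX17 147 ± 27.5 and 162 ± 23.2 CPM. KCNK17, a potassium channel, changed by -6.28 ± 0.80 and FCGBP by -3.39 ± 0.49. VANGL2 was the gene that was higher in KO, by 1.08 ± 0.17. In the cell cycle list 0 of 12 tested members passed (0 adjusted over the list alone), with adjusted p = 1e-06, and adjusted p = 0.331 with an estimated correlation towards higher levels. A total of 43 genes differed, 42 of them lower in KO. The libraries paired by replicate number, and the block gave 57 genes. DESeq2 called 77 genes, and limma-trend 12, with adjusted p = 0.104 to 0.671 for GFI1, SPN, CSF1R, LYZ and FCGBP. The 8 compared libraries alone gave 10 genes, with adjusted p = 0.0532 to 0.1 for RUNX1, BMX, CSF1R, LYZ and FCGBP. Without KO number 1, 28 genes passed.

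CD43-positive cells of day 12 differed from SOX17-positive endothelium in blood and vessel genes. In SOX17-negative CD43-positive cells (3 libraries) MPO was higher by 12.24 ± 0.33, PTPRC by 7.98 ± 0.36 and RUNX1 by 3.27 ± 0.26 than in endothelium (4 libraries). RUNX3 was higher by 9.60 ± 0.31. CLC, a granule protein without a count in endothelium, was at least 2150-fold higher. In the myeloid and mast cell list 16 of 16 tested members rose (16 adjusted over the list alone), with adjusted p = 4.12e-17, and adjusted p = 0.00168 with an estimated correlation. In the leukocyte list 11 of 12 tested members rose and 1 fell (11 rose and 1 fell adjusted over the list alone), with adjusted p = 3.31e-15, and adjusted p = 0.00111 with an estimated correlation, and SPN, the gate, differed by 7.46 ± 0.26. In the megakaryocyte list 12 of 12 tested members rose (12 adjusted over the list alone), with adjusted p = 2.17e-05, and adjusted p = 0.0455 with an estimated correlation, and PPBP was at least 1030-fold higher. In the cell cycle list 12 of 12 tested members rose (12 adjusted over the list alone), with adjusted p = 6.33e-06, and adjusted p = 0.194 with an estimated correlation, led by BUB1 at 2.77 ± 0.31. All endothelial members were lower, as 18 of 18 tested members fell (18 adjusted over the list alone), with adjusted p = 4.27e-26, and adjusted p = 0.000798 with an estimated correlation. CLDN5 differed by -8.49 ± 0.38 and EMCN by -7.54 ± 0.42. In the arterial list 14 of 15 tested members fell (15 adjusted over the list alone), with adjusted p = 5.4e-12, and adjusted p = 0.0299 with an estimated correlation, and GJA5, a connexin of arteries, differed by -9.33 ± 0.93. Among the HOXA and CDX genes 11 of 13 tested members fell (11 adjusted over the list alone), with adjusted p = 1.57e-05, and adjusted p = 0.0449 with an estimated correlation. The mitochondrial share was 8.65 ± 0.25 % in these cells and 4.57 ± 0.46 % in endothelium, and the 10 most abundant genes of a library held 7.80 ± 0.11 % and 5.15 ± 0.33 % of its counts. In all 15210 genes differed, 7429 of them higher in CD43-positive cells.

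SOX17-positive CD43-positive cells (2 libraries) held both kinds of transcripts, though RNA of pooled cells cannot tell whether the same cells held both. Against SOX17-positive endothelium MPO was higher by 9.67 ± 0.32, SPN by 6.73 ± 0.26 and RUNX1 by 2.55 ± 0.27. In the leukocyte list 11 of 12 tested members rose and 1 fell (11 rose and 1 fell adjusted over the list alone), with adjusted p = 5.42e-45, and adjusted p = 2.34e-06 with an estimated correlation, and among haematopoietic transcription factors 11 of 16 tested members rose (12 rose and 1 fell adjusted over the list alone), with adjusted p = 1.09e-15, and adjusted p = 0.000722 with an estimated correlation. CLDN5 differed by -1.33 ± 0.29. In the pan-endothelial list 15 of 18 tested members fell (17 adjusted over the list alone), with adjusted p = 1.65e-08, and adjusted p = 0.119 with an estimated correlation. CDH5 was 906 ± 92.6 CPM in these cells, 2073 ± 174 CPM in endothelium and 16.6 ± 11.1 CPM in SOX17-negative CD43-positive cells. The mitochondrial share was 6.85 ± 0.55 %. A total of 6086 genes differed, and 3857 without number 2 of the 2 libraries, where the lone library was assumed to vary like the other groups. Between the CD43-positive fractions 8619 genes differed, 3347 higher and 5272 lower without SOX17. HDC, histidine decarboxylase of mast cells and basophils, was higher without SOX17 by 4.03 ± 0.69 and CLC by 4.16 ± 0.47, although DESeq2 did not call them (adjusted p = 0.533 and 0.665). CLDN5 differed by -7.16 ± 0.38. In the pan-endothelial list 18 of 18 tested members fell (18 adjusted over the list alone), with adjusted p = 1.41e-43, and adjusted p = 7.34e-05 with an estimated correlation, and in the myeloid and mast cell list 13 of 16 tested members rose (13 adjusted over the list alone), with adjusted p = 1.34e-07, and adjusted p = 0.0256 with an estimated correlation. With the spread taken from these 5 libraries alone the count was 5683.

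Transcripts lower in KO endothelium of day 12 were compared with those of CD43-positive SOX17-negative cells. Of the 42 genes lower in KO, 30 were higher in CD43-positive cells than in WT endothelium, where 13.6 would be shared by chance, and 8 were lower. RUNX1, MYB, GFI1, SPI1, CSF1R and SPN are among the 30, while BMX and KCNK17 are not. With VANGL2, higher in KO and lower in CD43-positive cells, 31 genes lay opposite in both. Both comparisons use the same 4 WT endothelial libraries. With these libraries divided between the comparisons, 9 to 38 genes lay opposite, with a median of 18.5. The number of genes called lower in KO changed with the division, from 15 to 46, and 8 to 37 of them were higher in CD43-positive cells, where 4.3 to 13.2 would be shared by chance. The limit of the 13.6 holds for these values too.

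**Figure D2:**
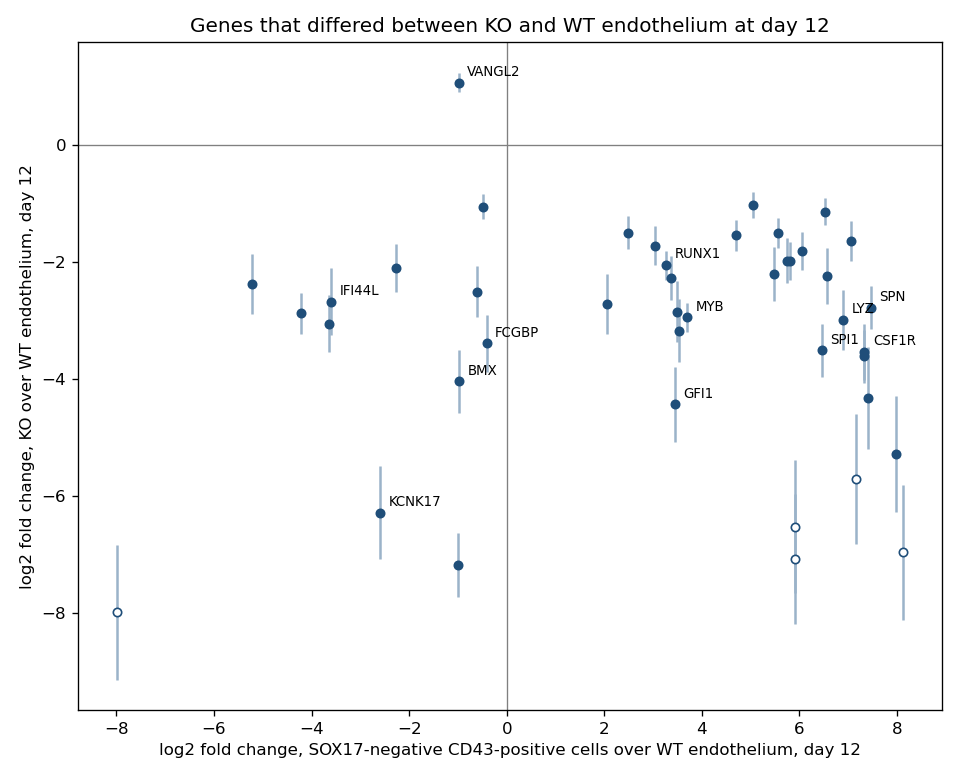
Log2 fold change of KO against WT SOX17-positive CD43-negative cells at day 12 (y axis, bars are standard errors) against that of SOX17-negative CD43-positive cells over WT endothelium (x axis) for the 43 genes that differed between KO and WT. Open circles mark genes without a count in a compared group, whose fitted value is no bound. Of the 42 genes below 0 on the y axis, 30 were called higher in CD43-positive cells and 8 lower.

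The endoderm protocol (3 WT libraries a day) opened with genes of endoderm, streak and lateral mesoderm together. From day 0 to day 2 SOX17, without a count at day 0, was at least 6360-fold higher and reached 409 ± 65.2 CPM. GATA6 was 8120-fold (95 % counting interval 2780 to 39400) higher, and LHX1 rose by 11.61 ± 0.27. In the definitive endoderm list 13 of 16 tested members rose and 1 fell (13 rose and 1 fell adjusted over the list alone), with adjusted p = 4.39e-50, and adjusted p = 9.6e-06 with an estimated correlation. In the primitive streak list 11 of 11 tested members rose (11 adjusted over the list alone), with adjusted p = 1.02e-34, and adjusted p = 0.000682 with an estimated correlation. In the lateral mesoderm list 6 of 9 tested members rose (6 adjusted over the list alone), with adjusted p = 5.78e-08, and adjusted p = 0.00269 with an estimated correlation. FGF17 rose by 12.28 ± 0.27 and MIXL1 by 8.37 ± 0.17. In the pluripotency list 12 of 14 tested members fell (12 adjusted over the list alone), with adjusted p = 1.51e-09, and adjusted p = 0.0138 with an estimated correlation, and UTF1 changed by -6.58 ± 0.41. CER1, a Nodal and BMP inhibitor, rose by 6.85 ± 0.15, and ID1, a BMP target, changed by -3.43 ± 0.26. In all 11955 genes changed, 6176 upwards. The mitochondrial share was 5.27 ± 0.25 % at day 0 and 5.96 ± 0.25 % at day 2.

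Between day 2 and day 4 of the endoderm protocol FRZB, a Wnt antagonist, rose by 6.33 ± 0.26, GATA4 by 3.00 ± 0.16 and FOXA1 by 2.52 ± 0.29. In the definitive endoderm list 11 of 16 tested members rose and 1 fell (11 rose and 1 fell adjusted over the list alone), with adjusted p = 1.42e-06, and adjusted p = 0.00749 with an estimated correlation. In the list of gut and hepatic endoderm 5 of 7 tested members rose (5 adjusted over the list alone), with adjusted p = 0.00113, and adjusted p = 0.0565 with an estimated correlation, led by APOA1, an apolipoprotein, at 4.75 ± 0.54. POU5F1 changed by -3.97 ± 0.43. Proliferation transcripts fell, as 11 of 12 tested members fell (11 adjusted over the list alone), with adjusted p = 7.29e-16, and adjusted p = 0.00351 with an estimated correlation. TOP2A changed by -1.77 ± 0.09 and MKI67 by -1.71 ± 0.09. In all 9132 genes changed, 4791 upwards, and the block by replicate number, which paired these libraries, gave 9276. From day 4 to day 7 4579 genes changed, 2413 upwards. In the cell cycle list 8 of 12 tested members rose (10 adjusted over the list alone), with adjusted p = 3.12e-07, and adjusted p = 0.0598 with an estimated correlation, led by PLK1 at 1.04 ± 0.11. ACTA2 and ACTC1, actins of muscle, rose by 6.64 ± 0.78 and 6.35 ± 0.44, and KLHL14 by 7.22 ± 0.45. In the primitive streak list 6 of 11 tested members fell (1 rose and 6 fell adjusted over the list alone), with adjusted p = 0.000346, and adjusted p = 0.144 with an estimated correlation. In the definitive endoderm list 5 of 16 tested members rose and 5 fell (7 rose and 6 fell adjusted over the list alone), with adjusted p = 0.89, and adjusted p = 0.892 with an estimated correlation, and SOX17 changed by -0.85 ± 0.11, to 236 ± 2.49 CPM. The 10 most abundant genes held 8.44 ± 0.63 % of the counts at day 7 and 6.72 ± 0.56 % at day 4.

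The early days of both protocols were compared as changes from their own day 0 in WT (3 endoderm and 4 mesoderm libraries a day). At day 2, HHEX differed by 6.06 ± 1.02 and PRDM1 by 5.57 ± 1.16 in favour of endoderm. FOXA2, a pioneer factor of endoderm, was 89.1 ± 14.4 CPM in endoderm and 0.0198 ± 0.0396 CPM in mesoderm, while SOX17 was 409 ± 65.2 and 22.82 ± 10.41 CPM. In the definitive endoderm list 8 of 16 tested members rose (9 adjusted over the list alone) relative to mesoderm, with adjusted p = 4.37e-09, and adjusted p = 0.000281 with an estimated correlation. BMP targets differed the other way, as 6 of 7 tested members fell (6 adjusted over the list alone), with adjusted p = 1.12e-15, and adjusted p = 0.000429 with an estimated correlation. MSX2 differed by -7.54 ± 1.17, BAMBI by -5.92 ± 0.30 and ID1 by -5.47 ± 0.49. Among Nodal targets 4 of 6 tested members rose and 1 fell (4 rose and 1 fell adjusted over the list alone), with adjusted p = 0.00071, and adjusted p = 0.0354 with an estimated correlation, led by LEFTY1 at 7.30 ± 0.64. BMP4 differed by -6.99 ± 0.52 and GATA2, a factor of blood and endothelium, by -7.58 ± 0.74.

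At day 4 Nodal targets differed as well, where 5 of 6 tested members rose and 1 fell (5 rose and 1 fell adjusted over the list alone), with adjusted p = 1.13e-12, and adjusted p = 0.000225 with an estimated correlation. LEFTY2 differed by 15.64 ± 0.56 and CER1 by 14.51 ± 0.89. In the definitive endoderm list 13 of 16 tested members rose (14 adjusted over the list alone), with adjusted p = 3.68e-13, and adjusted p = 4.41e-05 with an estimated correlation, and FOXA2 differed by 11.24 ± 0.68. Endothelial genes were lower in endoderm relative to mesoderm, as 1 of 17 tested members rose and 13 fell (1 rose and 13 fell adjusted over the list alone), with adjusted p = 4.6e-14, and adjusted p = 0.0116 with an estimated correlation. ERG differed by -8.83 ± 0.78 and FLT1 by -8.16 ± 0.50. In the BMP target list 1 of 7 tested members rose and 5 fell (1 rose and 5 fell adjusted over the list alone), with adjusted p = 1.54e-06, and adjusted p = 0.0103 with an estimated correlation, and BAMBI differed by -7.49 ± 0.32. In the cell cycle list 11 of 12 tested members fell (12 adjusted over the list alone), with adjusted p = 7.03e-08, and adjusted p = 0.0134 with an estimated correlation. The difference between protocols passed for 6683 genes at day 2 and 9163 at day 4. The unsorted libraries of both protocols have numbers of separate series, and endoderm d4 number 3 has a number of the sorted series, so no series holds unsorted libraries of both protocols. A difference between series that is the same on every day cancels at day 2, since each protocol is compared with its own day 0. At day 4 it cancels only in part, because endoderm d4 number 3 has no day 0 library of its series. Without that library 8438 genes passed at day 4. A difference between series that arises on later days cannot be told apart from the protocol. Undifferentiated cells of the experiments differed in 200 genes, 99 higher in the endoderm experiment, and their mitochondrial share was 5.27 ± 0.25 % there and 3.44 ± 0.56 % in the mesoderm experiment. The total of 200 became 7 without endoderm d0 number 3, 63 without number 2 and 86 without number 1. It was 396 without mesoderm d0 WT number 1 and 71 without number 2. DESeq2 called 634 genes and the 7 compared libraries alone 0.

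Endoderm of day 7 (3 libraries) and SOX17-positive endothelium of day 7 (4 WT libraries) held SOX17 at 236 ± 2.49 and 176 ± 32.4 CPM, a difference of 0.43 ± 0.12. CER1 differed by 16.92 ± 0.30 and GATA4 by 10.83 ± 0.21. FOXA2, without a count in endothelium, was at least 4220-fold higher. In the definitive endoderm list 15 of 16 tested members rose and 1 fell (15 rose and 1 fell adjusted over the list alone), with adjusted p = 7.78e-22, and adjusted p = 0.0135 with an estimated correlation. In the pan-endothelial list 18 of 18 tested members fell (18 adjusted over the list alone), with adjusted p = 4.62e-48, and adjusted p = 0.00513 with an estimated correlation. FLI1, an ETS factor, was at least 7490-fold lower and PECAM1 differed by -12.76 ± 0.22. Among the HOXA and CDX genes 13 of 13 tested members fell (13 adjusted over the list alone), with adjusted p = 1.65e-11, and adjusted p = 0.0218 with an estimated correlation, and HOXA9 was at least 2860-fold lower. RUNX1 differed by -6.44 ± 0.36 and TAL1 by -10.65 ± 0.29. A total of 15146 genes differed, 7472 higher in endoderm. Deviations paired by replicate number, and the block gave 15423 genes. With the block the definitive endoderm, pan-endothelial and HOXA and CDX lists had adjusted p = 2.24e-23, 1.86e-46 and 1.83e-14, and each had adjusted p = 0.139 with an estimated correlation, so these calls were lost there. The 10 most abundant genes held 8.44 ± 0.63 % of the counts in endoderm and 5.61 ± 0.33 % in endothelium. Lineage, sorting and library-number series coincide here.

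**Figure D3:**
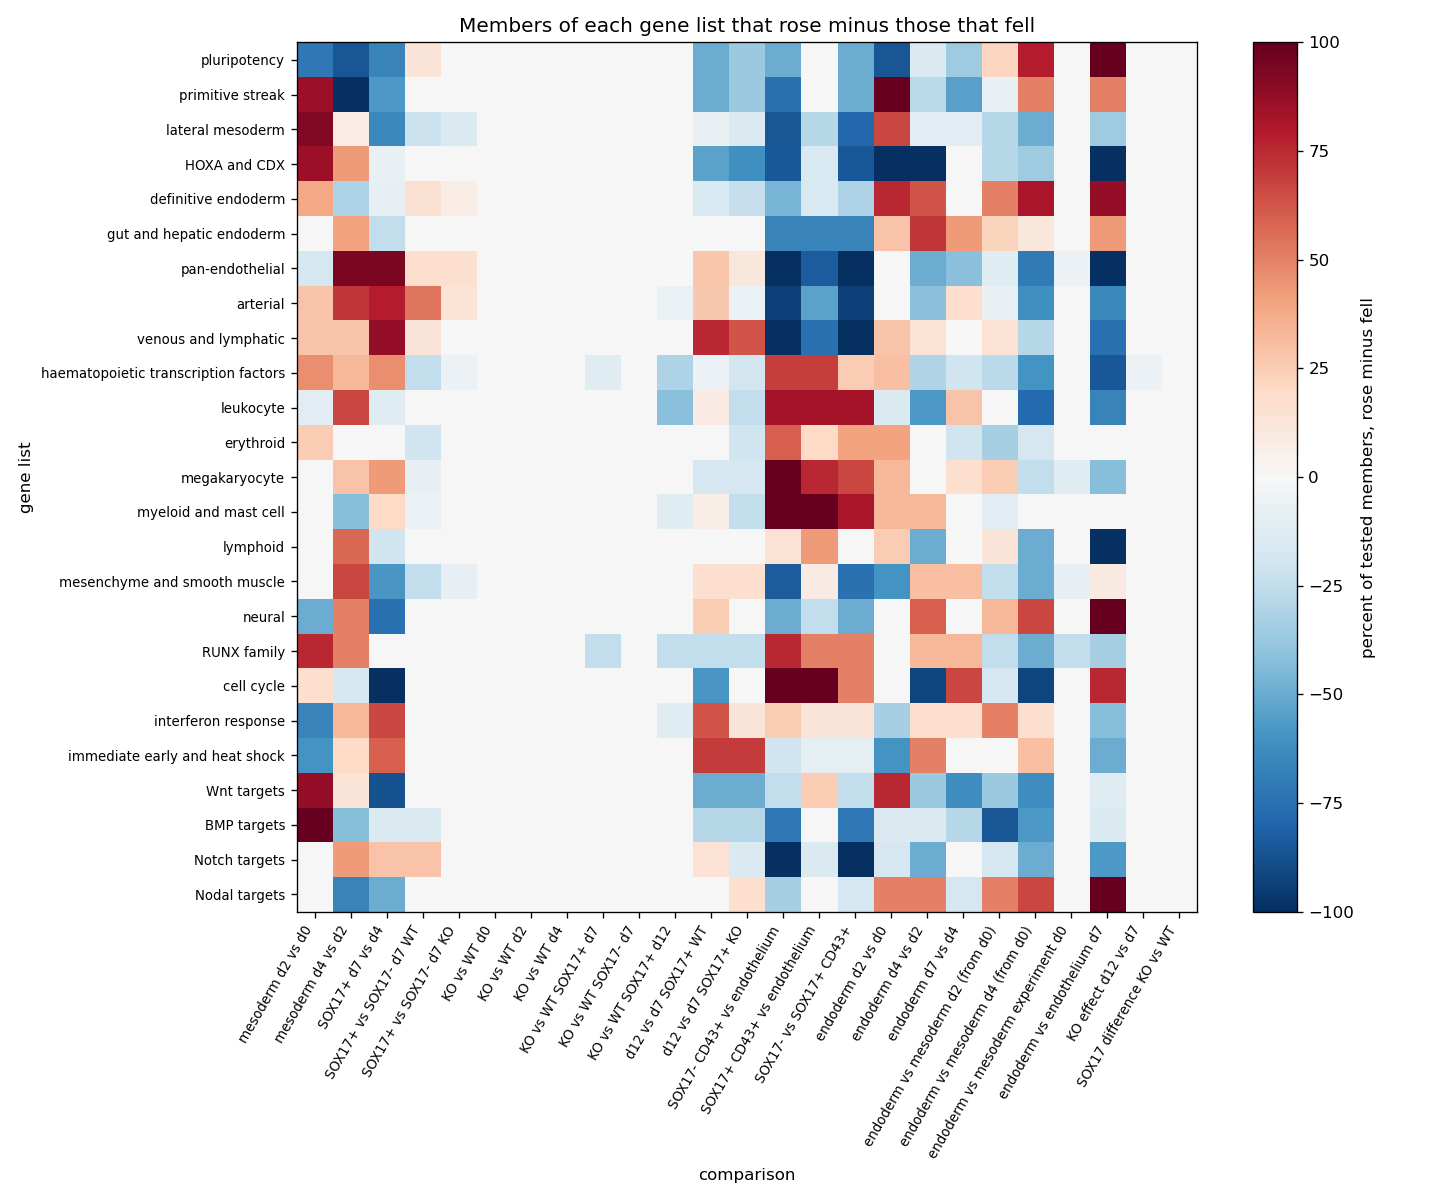
Share of tested members of each gene list that rose minus the share that fell, in percent (colour), for each comparison (columns) and list (lines). Blue cells are net lower, red cells net higher and white cells balanced or without a call.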

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

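The tests of explanations for the 3 patterns weighed here were all chosen after the result was seen, while the rules that picked out libraries and differences were fixed before the data were examined. GPAT3, H19, HSD17B7P2 and IL11 are named after their values were seen.

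Of 55 sets of 4 libraries and measures, 5 held 1 library far from the other 3, and chance alone gives about 1 in 20. RUNX1 was 7.67 CPM in d0 WT number 1 and 0.784 to 1.45 CPM in the other 3. In day 7 WT SOX17-positive cells RUNX1 was 148 CPM in number 3 and 87.2 to 92.8 CPM in the others. SOX17 was 0.0763 CPM in d0 WT number 2, from 1 count, and 0 in the others, while d0 KO numbers 2 and 3 also held 1 count each. In KO SOX17-positive cells of day 7 SOX17 was 229 CPM in number 4 and 171 to 178 CPM in the others. SPN was 1.43 CPM in d2 WT number 3 and 0.847 to 0.922 CPM in the others. Differences between groups were picked out for the change from day 0 between protocols, which passed for 6683 genes at day 2 and 9163 genes at day 4, and for the KO effect between day 7 and day 12, which passed for 1 gene, MYB.

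The 42 transcripts lower in KO endothelium of day 12 hold blood genes and others, and RNA of CD43-positive blood cells in the WT gate, which was set to exclude them, is argued against for 10, among them BMX, KCNK17, FCGBP and H19, which would need more than 100 % of such cells from either CD43-positive fraction. For the 30 genes higher in CD43-positive cells it stays open in part, with a median needed share of 3.25 %. The needs ran from 0.838 % for SPN to 13.5 % for RUNX1 and 51 % for GPAT3. All SPN RNA of the WT gate was 0.976 % of its level in SOX17-positive CD43-positive cells. SPN therefore allows no larger share of cells with the mean profile of that fraction. Such cells are argued against for RUNX1 and for MYB, which needs 7.67 %, while cells of another profile stay open. MPO, at 572 CPM in SOX17-positive CD43-positive cells, was 0.734 CPM in the WT gate, and its difference between WT and KO was 0.07 % of that level, as that of CYBB was 0.1 %, but the 50 most abundant blood transcripts outside the pattern, both included, differed by a median of 1.39 %, and blood cells low in CD43 were not isolated. A difference of the day 12 size already present in undifferentiated cells is argued against for 10 of the 14 genes that d0 WT cells held at 1 CPM or more. Their log2 fold change at day 0 lay more than 2 standard errors of the difference above that at day 12. The median log2 fold change of the 14, RUNX1 among them, was -0.13 at day 0 and -2.01 at day 12. The genes were chosen by their day 12 values, which can overstate these, so a smaller difference from day 0 onwards stays open. Loss of RUNX1 function remains open as a hypothesis, with 37 of the 42 genes below 0 already at day 7, since 1 KO derivative cannot separate it from other differences between the lines.

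HSD17B7P2, a pseudogene, was low in KO throughout. In all 6 pairs of groups every KO library lay below every WT library, which is the observation itself and no separate test of a difference between the lines from undifferentiated cells onwards. That explanation and loss of RUNX1 function cannot be told apart, because RUNX1 was present at low level at day 0 and there is 1 KO derivative. At day 0 the ratio of WT to KO had a 95 % counting interval from 2.35 to 40.2 around 7.75, from 24 and 3 counts (exact binomial test, p = 5.19e-05). The interval and the p-value cover counting error alone and not the spread between libraries. They also leave out that the gene was picked after its values were seen. The low level in KO-titled libraries of day 2 (0.0631 CPM against 0.473 CPM in WT) and day 4 (0.0145 against 0.404 CPM) goes with their titles.

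Library number 1 of day 0 stood apart in WT and KO, and its deviations correlated by 0.87 between the genotypes across 14869 genes, which are not independent replicates. RNA of cells like those of day 2 is argued against in WT. The 24 rising genes of streak and lateral mesoderm allow a median of 0 % of day 2 RNA, where RUNX1 would need 68.6 %. RNA of cells of later days was not tested. A shared state of these cultures or libraries with raised immediate early genes stays open, since it was formed from these genes, of which 8 of the 10 in the immediate early and heat shock list were highest in number 1 in both genotypes. IL11 was 145 and 97.7 CPM in WT and KO number 1, and 2.22 to 6.04 CPM in the other d0 libraries. Handling of the cultures and a library effect were not tested.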

How the results depend on the processing

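The alternatives were fixed before the data were examined, except that leaving out d0 number 1 of both genotypes, or d4 WT number 3 with d4 KO number 4, and the list tests without gate genes, without d7 WT SOX17-negative number 4 or with library runs as a block, were chosen after seeing the data. Of the counts of genes, 128 stayed within 1.5 times under the settings other than leaving out a library and 36 moved further. Median-of-ratios size factors and the choices made after seeing the data moved none of the counts they were run on. Size factors shifted the share of genes called higher by at most 6.2 points. Without d0 number 1, 10449 genes changed between day 0 and day 2, and edgeR called 0 genes between KO and WT at day 0 (455 with an unadjusted p under 0.05). Without the libraries of day 4 it called 0 genes between KO and WT at day 4 (1199 unadjusted). Of 171 named gene values, 147 kept direction and side of the threshold under every alternative run and 154 under every setting apart from left-out libraries. Several genes that met the rule for naming, among them UNC5B, NFE2 and PRTN3, were left out of the text after their calls had ended under an alternative, so these shares are higher than for all genes the rule allows. The only value to turn was RUNX1 between SOX17 fractions of day 7 in WT, which did not pass, with a log2 fold change of -0.12 without SOX17-positive number 3 and 0.19 at most.

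Where counts moved, the cause was not tested, except that the filter on low counts changes how many genes are tested and leaving out a library leaves fewer samples. Without a filter on low counts the count became 341 for d0 between experiments, 34 for KO in SOX17-positive and 24 in SOX17-negative cells of day 7, 96 for KO at day 12, 651 and 446 for SOX17 in WT and KO, and 11 for the KO effect between days. DESeq2 gave 634, 30, 13, 77 and 8 for these in the same order without the SOX17 comparisons, 333 for SOX17 in KO, and 15 and 2 for KO at day 2 and day 4. Limma-trend gave 325 for d0 between experiments, 1 for KO at day 4, 8 for KO in SOX17-negative cells, 12 for KO at day 12, 234 for SOX17 in KO and 0 for the KO effect between days.

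The compared groups alone gave 0 genes for d0 between experiments, 143 for KO at day 2, 10 for KO at day 12, 208 and 612 for SOX17 in WT and KO, and 5683 between the CD43-positive fractions. Replicate number as a block gave 7 for KO in SOX17-negative cells, 559 and 311 for SOX17 in WT and KO and 6 for the KO effect between days. With that block Notch targets in KO at day 12 passed with camera, at adjusted p = 0.00988 in place of 0.0957, and adjusted p = 0.218 with an estimated correlation. With an estimated correlation the block ended the calls of Nodal targets between protocols at day 2 (adjusted p = 0.146) and of lateral mesoderm and Wnt targets between day 7 and day 4 (adjusted p = 0.0788 for each). Calls of other lists, such as lateral mesoderm between protocols at day 2 and Wnt targets at day 4, were lost too, and some were gained. The block of library runs gave 22, 7, 616, 376 and 3 for KO in SOX17-positive and SOX17-negative cells, SOX17 in WT and KO and the KO effect between days. Leaving SOX17, SPN and CD34 out of the lists where they are the gate ended the calls of definitive endoderm between SOX17 fractions in WT (adjusted p = 0.216) and KO (adjusted p = 0.107) and no other call in the 8 comparisons run. With an estimated correlation 84 of the 196 list calls held. With the WT endothelial libraries divided, the overlap had a median of 18.5 in place of 31, while the genes called lower in KO also changed, from 15 to 46 in place of 42.

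With 1 library left out, 179 counts stayed within 1.5 times and 32 moved further. The range was 7 to 396 for d0 between experiments, 0 to 3 for KO at day 4, 2 to 11 for KO in SOX17-positive and 1 to 2 in SOX17-negative cells of day 7, 28 to 52 for KO at day 12, 166 to 407 for SOX17 in WT and 46 to 160 in KO, 3857 to 5727 for the 2 SOX17-positive CD43-positive libraries against endothelium, and 1 to 6 for the KO effect between days. Leaving 1 library in a group of 2 assumes that it varies like the other groups. Depth limits genes near 0 counts, for which bounds or ratios replace the fitted fold.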

Other observations

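The tests over other splits of the libraries were written after the results were seen, and the gene lists described first were fixed before the data were examined.

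Notch targets and venous genes were lower in CD43-positive SOX17-negative cells of day 12 (3 libraries) than in SOX17-positive endothelium (4 WT libraries), while lymphoid and erythroid genes went both ways and did not pass as lists. In the Notch target list 7 of 7 tested members fell (7 adjusted over the list alone), with adjusted p = 0.000151, and adjusted p = 0.0979 with an estimated correlation. DLL4, a Notch ligand, differed by -8.98 ± 0.52 and HEY1, a Notch effector, by -7.09 ± 0.56. In the venous and lymphatic list 8 of 8 tested members fell (8 adjusted over the list alone), with adjusted p = 2.58e-08, and adjusted p = 0.0299 with an estimated correlation. APLNR differed by -8.32 ± 0.58 and NR2F2, a nuclear receptor of veins, by -7.51 ± 0.43. In the lymphoid list 4 of 7 tested members rose and 3 fell (4 rose and 3 fell adjusted over the list alone), with adjusted p = 0.355, and adjusted p = 0.512 with an estimated correlation. CD7, an antigen of T and NK cells, was higher by 7.36 ± 0.56, while RAG1, a recombinase subunit, differed by -1.81 ± 0.24. In the erythroid list 4 of 5 tested members rose and 1 fell (4 rose and 1 fell adjusted over the list alone), with adjusted p = 0.488, and adjusted p = 0.6 with an estimated correlation. KLF1, without a count in endothelium, was at least 52-fold higher, and EPOR, the erythropoietin receptor, differed by -2.48 ± 0.23.

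SOX17-positive endothelium of day 7 held more RNA of interferon and immediate early genes than unsorted cells of day 4 (4 WT libraries each). In the interferon response list 4 of 6 tested members rose (4 adjusted over the list alone), with adjusted p = 0.00759, and adjusted p = 0.126 with an estimated correlation, and IFIT3 was higher by 4.31 ± 0.18. In the list of immediate early and heat shock genes 7 of 10 tested members rose and 1 fell (7 rose and 1 fell adjusted over the list alone), with adjusted p = 0.0135, and adjusted p = 0.309 with an estimated correlation. FOSB was higher by 7.11 ± 1.01 and FOS by 5.68 ± 0.76, while ATF3 differed by -2.80 ± 0.28. Sorting coincides with day here. Against the same endothelium, endoderm of day 7 (3 libraries) was higher in the neural list, where 4 of 4 tested members rose (4 adjusted over the list alone), with adjusted p = 0.0013, and adjusted p = 0.0495 with an estimated correlation. With replicate number as a block the neural list had adjusted p = 7.1e-05, and adjusted p = 0.16 with an estimated correlation. STMN2, of neuronal microtubules, differed by 7.45 ± 0.26 and PAX6 by 4.49 ± 0.27.

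The single KO SOX17-negative CD43-negative library of day 12 was in no comparison. It held CDH5 at 1669 CPM, CD34 at 1685 CPM and COL3A1 at 799 CPM. RUNX1 was 16.7 CPM, SOX17 31.1 CPM and MYB 8.23 CPM. SPN was 2.46 CPM, and PTPRC and HSD17B7P2 had 0 counts.

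Other splits were fitted on the compared libraries alone, which also changes the count of the real split. In 5 comparisons the real split alone, 1 of 35 with itself counted, gave as many genes and no other split gave more than 0. The real split gave 8853 genes for mesoderm of day 2 against day 0 and 10422 for day 4 against day 2. It gave 12586 for day 7 against day 4, 3235 for day 12 against day 7 in KO and 14423 for CD43-positive SOX17-negative cells. For day 2 against day 0 and day 7 against day 4, no pair of libraries correlated by over 0.1. Only there is chance called excluded, at a share not adjusted over the comparisons. By replicate number 2 of 4 pairs lay over 0.1 for day 4 against day 2 (0.07 to 0.14) and for KO over time (0.05 to 0.36). By library run 2 of 3 did for CD43-positive SOX17-negative cells (0.04 to 0.35). For SOX17 at day 7 in WT the real split gave 208 genes and at most 2 came from another split. There 3 of 4 pairs by replicate number correlated by over 0.1, with the lowest at -0.02. The splits do not allow for such partial pairing, so chance is not called excluded there or in the comparisons above that hold such pairs. In 3 comparisons the replicate numbers paired the libraries, and the real split was again the only 1 of 35 as large, with 9 genes for KO at day 7 in SOX17-positive cells, 5303 for day 12 against day 7 in WT and 15146 for endoderm against endothelium of day 7, and at most 0 in another split. In 2 others library runs paired the libraries, with 612 genes and at most 14 in another of 35 splits for SOX17 at day 7 in KO, and 2 genes and at most 1 for KO at day 7 in SOX17-negative cells. In each of these paired comparisons the splits that part as many pairs number 8, the real one included, with at most 0 genes in another, and are too few for a share under 0.05. For the difference between protocols 50 splits were drawn. At day 2 the real split gave 7349 genes and the highest other 6855, and at day 4 it gave 7983, with 2 splits as large and 8275 in the highest. These splits regrouped libraries of groups that differ strongly themselves, so they do not stand for the absence of a difference between protocols. They cannot decide on chance here. For endoderm alone 10 splits are too few, with 12356, 8161 and 3203 genes in the real split for successive days and at most 0 in another. Comparisons with the group of 2 were not split.

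Chance was not excluded for the other comparisons. All 35 splits were as large for KO at day 0 (0 genes, highest other 1), KO at day 4 (0 and 7) and d0 between experiments (0 and 72). For KO at day 2, 2 splits reached the real 143 genes, and the split that exchanged WT number 2 and KO number 4 gave 224. For KO at day 12, 4 splits were as large as the real 10 genes. The highest gave 300 and set numbers 1 and 3 of both genotypes against numbers 2 and 4, which points to a structure of the samples by replicate number. With that number as a block 57 genes passed. As numbers paired the libraries of KO at day 0, day 2, day 7 SOX17-positive and day 12, the real split was set against the others of the 8 that part all 4 pairs, which gave at most 0 genes in each, as did those for WT over time. These 8 are too few for a share under 0.05. The others kept both members of a pair on 1 side. The KO effect between days had 7 of 50 splits as large as its 1 gene, with 11 in the highest, and the SOX17 difference between genotypes had all 50 at 0.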
